A study of Anopheles gambiae with 4 samples.

How the data were processed

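RNA from the fat body of adult female Anopheles gambiae was measured on 4 single-channel Affymetrix Plasmodium/Anopheles arrays, with one array per RNA sample. The groups came from the sample titles: 2 arrays from females injected with a CpG oligodeoxynucleotide (CpG-ODN) and 2 from females injected with elution buffer. The series text speaks of 2 independent experiments per treatment. The labels do not say that arrays with the same replicate number came from one experiment. The p-values rest on the spread among these samples, much of it borrowed from other probe sets as described below.

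The authors deposited 1 table of signal intensity values on a linear scale, with one value per probe set and array. Per the submitters' processing notes the values were made with MAS5, Affymetrix's algorithm that combines the probes of a probe set into one background-corrected signal and scales each array. Its version, its scaling target and the annotation are not given in the sources used here, and detection calls were not used here. The trimmed mean per array, leaving out 2% at each end, ran from 139.9 to 144 signal units. The lowest value was 1, which 7 to 25 probe sets per array held. The number of arrays, 2 per group, limits the precision.

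The table held 17965 probe sets. Of these, 16884 had an ID starting with Ag., 937 had an ID built on a GenBank-style accession, and 144 were Affymetrix control probe sets. The files do not pair probe sets with genes, and 0 of the 456 accessions in the IDs matched the reference table of 15165 genes, so no gene is named. For the same reason the 25 gene lists drawn up for immunity, metabolism, stress and markers of other tissues were not used, and carry-over from other tissues was not assessed.

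The groups, the comparison of CpG-ODN with buffer and its test, the filters, the gene lists and the rule for named genes were fixed before the data were examined. The comparison of replicate 1 with replicate 2 and the correlation of the changes in the replicates were chosen after seeing the data. Values were taken as log2 with no pseudocount. The deposited scaling was kept, because the array medians of the Ag. probe sets lay within 0.07 log2 of each other and the plan allowed 0.3. The planned filter was a percentile of Plasmodium probe sets, which were not analysed here apart from 7 control IDs, and the planned comparison of those probe sets was not run. The fallback in the plan was used: the 8442 Ag. probe sets in the upper 50% by mean log2 signal over the 4 arrays, above a signal of 69.5. As a background level, chosen after seeing the data, the 95th percentile of 24 control probe sets (Affymetrix tag controls and the Plasmodium actin and Gapdh controls) was taken per array. It lay between 53.2 and 80.3 signal units.

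Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a trend of the spread on brightness), two-sided, with Benjamini-Hochberg adjustment over the 8442 probe sets and a threshold of 0.05. The fit as planned left the replicate number out of the model and had 2 residual degrees of freedom. A fit with the replicate number as a block had 1. In addition, eBayes borrowed spread from the other probe sets, worth 2.91 prior degrees of freedom without the block and 6.11 with it. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333, so none was run for single probe sets.

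Same-numbered arrays deviated together, with a correlation of their deviations from the group means of 0.664 across probe sets. The hybridisation controls, which do not come from the mosquitoes, also separated the replicate numbers. The replicate number was therefore treated as an array batch seen in the data, and results are given without it, with it as a block, and within each replicate number.

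Both fits were tested on simulated data: 20 simulations for the comparison of CpG-ODN with buffer, each with 200 of 8442 probe sets changed. Without the block, 3.65% of the 2-fold and 80.4% of the 4-fold changes were recovered, and 0.105% of the calls were false. With the block, 96.0% and 99.9% were recovered, and 9.47% of the calls were false, above the nominal rate. In simulations with no change, the blocked fit called 0.6 probe sets on average and 4 at most. The simulated noise was normal, was drawn from the spread that the blocked fit had estimated, and was added to a purely additive replicate difference. These data thus met the assumptions of the blocked fit, so its simulated rates are not error rates for its calls on the real arrays.

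The rule for named genes took called probe sets first. Where a direction had fewer than 12, it went on by smallest unadjusted p among probe sets with at least a 2-fold change and groups that did not overlap. Without gene names, the first 2 probe sets in each direction are identified by their IDs. Where the dimmer group lay under the background level on both arrays, the fold is given as a lower bound, the brighter group's mean log2 signal against that level. The alternatives tried were quantile normalization, median centring, no filter, log2(signal + 64), no trend, a robust fit, a 2-fold minimum, the replicate block and leaving out each array. Cyclic loess, a filter at the background level, a stricter brightness filter and the block combined with other settings were added after seeing the data.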

Results

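The series addressed how the fat body of Anopheles gambiae, a vector of malaria, responds to an injected CpG oligodeoxynucleotide (CpG-ODN). The fat body is the insect counterpart of liver and adipose tissue and secretes many of the immune proteins of the haemolymph. CpG oligodeoxynucleotides are short synthetic DNAs with an unmethylated CG step, used in vertebrates as immune stimulants. The one used here, named 0604, had the sequence TCCATGACGTTCCTGATGCT, which is 20 nt long and holds 1 CG step. The sample descriptions spell the name 0640, and it was taken to be the same oligonucleotide. Females received 69 nL of a 0.1 mM solution into the thorax, which is 6.9 pmol, or the same volume of buffer. After 18 h, pools of 20 to 30 fat bodies were taken for RNA, and 3.7 µg of total RNA was used per array. Each group had 2 arrays, replicates 1 and 2 by their titles, which the descriptions number 1 and 3.

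The 4 arrays were closely matched in overall brightness. The median signal of the 16884 Ag. probe sets was 69.7 and 67.2 on the CpG-ODN arrays and 70.5 and 70.7 on the buffer arrays. Of these probe sets, 43.6% lay above the background level on all 4 arrays, against 87.2% of the 8442 brighter probe sets that were tested.

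The comparison of CpG-ODN with buffer asked which transcripts of the fat body differed after 18 h. Without the replicate number in the model, limma called 0 of the 8442 probe sets, with a smallest adjusted p of 0.9999. With the replicate number as a block, limma called 21 probe sets, of which 16 rose with CpG-ODN and 5 fell. In part that fit takes its error from the difference between the replicates' changes, which makes it favour probe sets that moved alike in both. The larger part was borrowed from probe sets of like brightness, with 6.11 prior degrees of freedom against 1 residual. Of the 16 that rose, 15 did so by 1.33-fold to 2.59-fold, and for 1, whose buffer signal lay under background, only a lower bound of 2.70-fold holds. With that bound the median was 2.03-fold, and 8 reached 2-fold. The 5 that fell differed by 2.07-fold to 3.22-fold with a median of 2.73-fold. The groups did not overlap for all 16 that rose, but for only 4 of the 5 that fell. Probe sets that rose had a median signal of 1165 and those that fell 305, against 147 over all tested. Of the 21, 4 had IDs ending in _s_at or _x_at, which mark probe sets that can bind several transcripts. IDs ending in _a_at, held by 6 of the higher calls, were not counted among these 4.

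Among the probe sets higher with CpG-ODN, Ag.2R.1440.0_CDS_at had the smallest p. Its log2 signal was 7.40 ± 0.19 (SD, n = 2) with CpG-ODN and 5.49 ± 0.16 (SD, n = 2) with buffer. The buffer signal lay under the background level on both arrays, so the probe set was at least 2.70-fold higher with CpG-ODN. Against that level the log2 change was at least 1.43 in each replicate. Ag.2R.65.0_CDS_a_at stood at 8.25 ± 0.32 (SD, n = 2) with CpG-ODN and 6.88 ± 0.08 (SD, n = 2) with buffer. Its log2 change was 1.37, with 1.21 in replicate 1 and 1.54 in replicate 2.

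Among the probe sets lower with CpG-ODN, Ag.UNKN.267.0_CDS_at was at 7.06 ± 0.21 (SD, n = 2) with CpG-ODN and 8.75 ± 0.16 (SD, n = 2) with buffer. Its log2 change was −1.68, with −1.65 in replicate 1 and −1.72 in replicate 2. Ag.3L.178.0_CDS_s_at, which can bind several transcripts, was at 8.89 ± 0.07 (SD, n = 2) with CpG-ODN and 9.93 ± 0.19 (SD, n = 2) with buffer. Its log2 change was −1.05, with −0.96 in replicate 1 and −1.14 in replicate 2.

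None of these 4 passed without the block, where the limma adjusted p was 0.9999 for each and the standard errors of the log2 changes were 0.18 and 0.20 for the higher pair and 0.18 and 0.16 for the lower pair. With the block, the limma adjusted p was 0.00504 for Ag.2R.1440.0_CDS_at (SE 0.12) and 0.0144 for Ag.2R.65.0_CDS_a_at (SE 0.13). It was 0.00581 for Ag.UNKN.267.0_CDS_at (SE 0.12) and 0.0277 for Ag.3L.178.0_CDS_s_at (SE 0.12). For Ag.2R.1440.0_CDS_at these tests and SEs belong to the log2 change as measured, 1.91, which uses buffer signals under background, and not to the bound. Over the 10 blocked settings in which they were tested, the call ended in 5 for Ag.3L.178.0_CDS_s_at and in 3 for Ag.2R.65.0_CDS_a_at. After quantile normalization, for example, their limma adjusted p was 0.0759 and 0.0501, while the log2 changes stayed at −1.09 and 1.39. The naming rule was met by 14 probe sets higher and 5 lower with CpG-ODN.

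**Figure D1:**
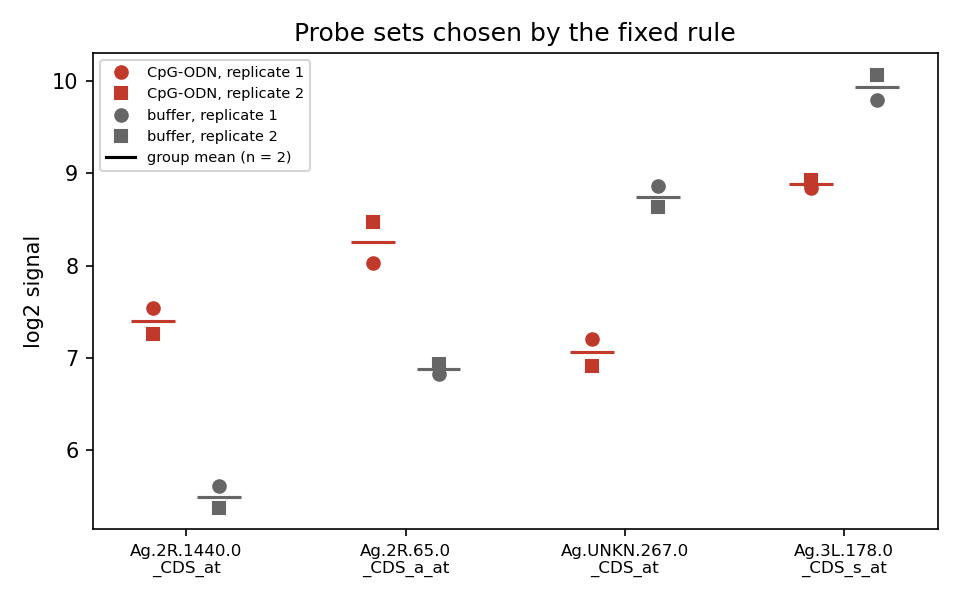
Log2 signal (vertical axis) of the 4 probe sets chosen by the rule (horizontal axis), with circles for replicate 1, squares for replicate 2, CpG-ODN in red, buffer in grey, and a line at each group mean (n = 2, no error bars). Both CpG-ODN arrays lie above both buffer arrays for the first 2 probe sets and below both for the last 2; the buffer values of the first lie under the background level.

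At an unadjusted p below 0.05, limma without the block had 152 probe sets and with it 818, and the groups did not overlap for 25.6% of the probe sets (1032 higher and 1125 lower with CpG-ODN). For 4 exchangeable arrays chance gives 422.1 and 33.3%. Same-numbered arrays deviated together, so these are not the no-effect values for the unblocked count or the share without overlap. The block removes that shared deviation, so 422.1 is the reference for the 818 if the error model of that fit held, which was not tested. Probe sets are not independent of each other, and the excess over 422.1 was not tested either. Simulated 2-fold changes were recovered in 3.65% of cases without the block, so under the settings of the simulation that fit missed most changes of that size. The rate on the real arrays is not known. The blocked calls rested on 1 residual degree of freedom and on spread borrowed from other probe sets, and they moved with the scaling. The share of higher calls was 76.2% as deposited (16 higher, 5 lower) and 40% after quantile normalization (2 and 3). It was 63.6% after median centring (7 and 4) and 42.9% after cyclic loess (3 and 4).

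The changes in the replicates were positively related across the 8442 probe sets, which are not independent of each other. Pearson's r between the change in replicate 1 and in replicate 2 was 0.206 and Spearman's rho was 0.231, and 58.7% of the probe sets had the same sign in both. With no filter, over all 16884 Ag. probe sets, Pearson's r was 0.0534. Over 4 equal groups by brightness, r was 0.0441, 0.126, 0.204 and 0.348 from the dimmest to the brightest. At least a 2-fold difference in both replicates was seen in 6 probe sets that were higher, 5 that were lower and 5 that went in opposite directions. At 1.5-fold, 31 were higher in both, 9 were lower in both and 18 were opposite. Unrelated changes would give 0.07, 0.07 and 0.14 at 2-fold and 2.13, 1.23 and 3.27 at 1.5-fold. The opposite pairs exceeded their count as well, so the excess alone does not show a shared response. The SD of the change over probe sets was 0.20 log2 in replicate 1 and 0.31 in replicate 2.

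**Figure D2:**
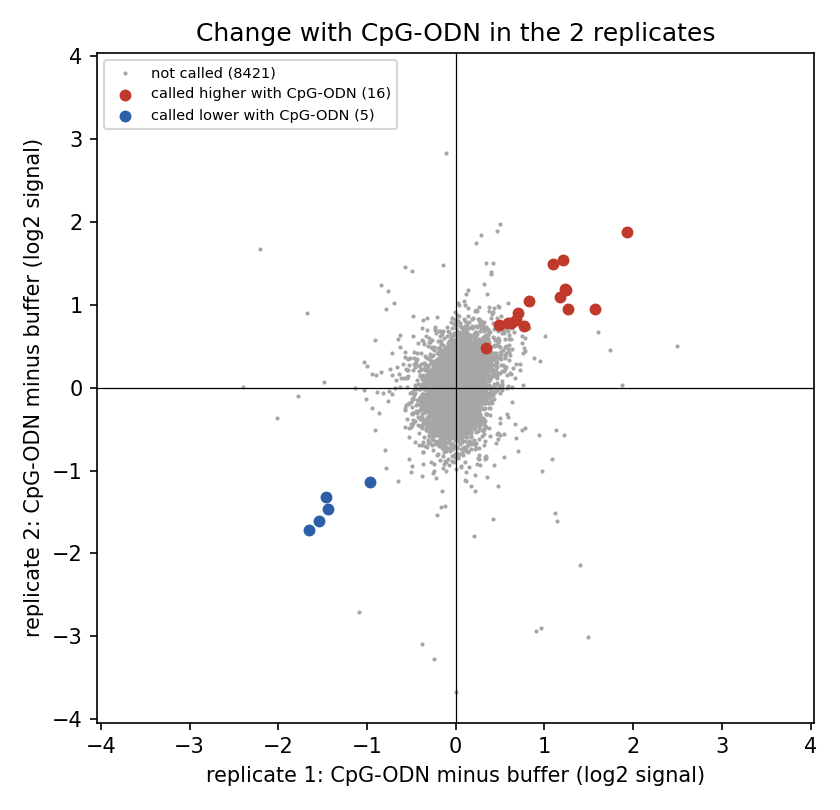
Difference between CpG-ODN and buffer in log2 signal for each of the 8442 tested probe sets (points), in replicate 1 (horizontal axis) against replicate 2 (vertical axis). Red and blue points are the 16 higher and 5 lower probe sets called by limma with the replicate number as a block. That fit in part favours probe sets with like changes in both replicates. The red point farthest to the upper right is Ag.2R.1440.0_CDS_at, whose buffer signal lay under background.

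Arrays resembled each other by replicate number more than by treatment. Over the tested probe sets, Pearson's r of the log2 signals was 0.990 between CpG-ODN and buffer in replicate 1 and 0.977 in replicate 2. It was 0.967 between the CpG-ODN arrays and 0.955 between the buffer arrays. In a limma comparison of replicate 1 with replicate 2, 281 probe sets were called, 131 brighter in replicate 1 and 150 dimmer. With treatment as a block, the form that matches the blocked comparison of CpG-ODN with buffer, 1061 were called, 556 brighter and 505 dimmer.

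The control probe sets for RNAs added during the protocol also differed by replicate number. The 9 hybridisation controls (bioB, bioC, bioD and cre, added with the labelled RNA) were brighter in replicate 1 by 0.67 log2 among buffer arrays and 0.66 among CpG-ODN arrays. After quantile normalization these differences were 0.64 and 0.61, and after median centring 0.67 and 0.60. For the 12 poly-A controls, which are added to RNA before labelling, replicate 1 minus replicate 2 was −0.13 among buffer arrays and −0.55 among CpG-ODN arrays. These controls lay near background on the replicate 1 arrays and farther above it on the replicate 2 arrays, which limits that reading. In replicates 1 and 2 their mean log2 was 6.34 and 6.89 with CpG-ODN, against background levels of 6.33 and 5.73. With buffer it was 6.44 and 6.57, against 6.11 and 5.83. The ratio of the 3′ to the 5′ probe set, a measure of how complete the labelled RNA was, was 1.84 and 1.66 for actin with CpG-ODN and 1.80 and 1.23 with buffer. For Gapdh, a glycolytic enzyme, it was 2.73 and 2.32 with CpG-ODN and 3.00 and 2.32 with buffer. The controls also differed between treatments. CpG-ODN minus buffer in replicates 1 and 2 was 0.12 and 0.13 log2 for the hybridisation controls and −0.10 and 0.32 for the poly-A controls. It was −0.07 and −0.15 for the actin controls and 0.07 and 0.12 for the Gapdh controls.

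**Figure D3:**
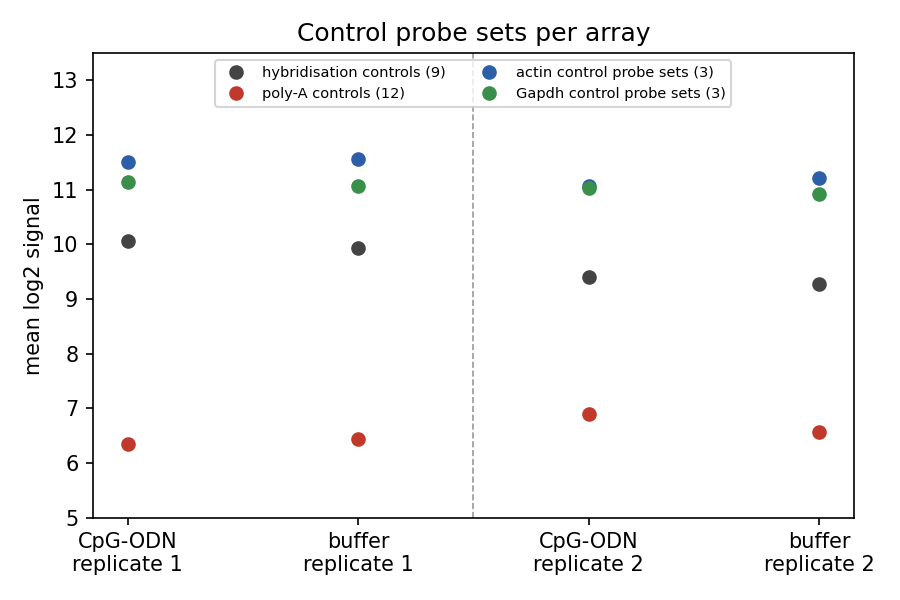
Mean log2 signal (vertical axis) of 4 kinds of control probe sets on each of the 4 arrays (horizontal axis), with the number of probe sets of each kind in the legend and no error bars. The hybridisation controls sit at 10.05 and 9.93 on the replicate 1 arrays and at 9.40 and 9.27 on the replicate 2 arrays.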

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

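The tests of the accession-based probe sets in this part were chosen only after the data were seen. The 937 probe sets with accession-based IDs were outside the comparison, and their organism is not given in the sources used here. They were dim, with median signals of 8.15 to 9.86 per array, and 3.74% of them lay above background on all arrays. Among them limma called 0 without the replicate block (16 at an unadjusted p below 0.05) and 10 with it. Of the 10, 3 did not clear the background level on both arrays of their brighter group, 4 did and were lower with CpG-ODN, and 3 did and were higher. The smallest adjusted p of this blocked fit was 4.67e-79, which 1 residual degree of freedom cannot carry, so its calls are not reliable and only values are given.

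The 3 higher ones drew attention as signal above the buffer arrays in data outside the comparison, and were picked by that fit. The first stood at 11.37 ± 0.17 (SD, n = 2) log2 with CpG-ODN and 10.46 ± 0.02 (SD, n = 2) with buffer, a difference of 0.91. The second differed by 0.67, from 7.27 ± 0.49 (SD, n = 2) with buffer to 7.93 ± 0.11 (SD, n = 2). The third also differed by 0.67, but its groups overlapped: it was at 7.24 and 6.19 with CpG-ODN and at 6.60 and 5.50 with buffer, the last under background. Without the block the limma adjusted p was 0.999 for each. Of the 4 lower ones, the first had both CpG-ODN signals under background and was at least 1.30-fold lower. The groups overlapped for the other 3. The second was at 9.46 with CpG-ODN and 9.39 with buffer in replicate 1, and at 5.26, under background, and 8.29 in replicate 2. In replicates 1 and 2, CpG-ODN minus buffer was −0.02 and −2.69 log2 for the third and −1.46 and 0.17 for the fourth, so each of these 3 differed mainly in a single replicate.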

How the results depend on the processing

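Cyclic loess, the background and stricter brightness filters and all settings combined with the block were chosen only after the data were seen. Without the block, limma called 0 higher and 0 lower under quantile normalization, median centring, cyclic loess, each filter, log2(signal + 64), no trend, a robust fit and a 2-fold minimum, and when any 1 array was left out (range 0 to 0; the lone array was assumed to vary like the other group). The count at an unadjusted p below 0.05 ran from 74 without CpG-ODN replicate 2 to 618 without buffer replicate 1. With the replicate block there were 16 higher and 5 lower. A rule with no test, 2-fold in all 4 pairs of arrays, gave 2 higher and 2 lower.

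The blocked counts moved under quantile normalization (2 higher, 3 lower), median centring (7 higher) and cyclic loess (3 higher). They also moved under log2(signal + 64) (9 higher), no trend (3 higher) and the stricter filter (5 higher, from 4221 probe sets). The causes were not tested, except that the stricter filter left only 18 of the 21 among the tested probe sets. A 2-fold minimum gave 8 higher because by its rule it keeps only calls of at least 2-fold. Of the 21, 5 remained called after quantile normalization, 7 after cyclic loess and 7 without the trend. All 21 kept their direction after quantile normalization and after cyclic loess. Their changes stayed about as large: the median log2 change of the higher and lower ones was 1.02 and −1.45 as reported. It was 0.95 and −1.47 after quantile normalization and 0.98 and −1.46 after cyclic loess. Leaving out the trend alters only the error, not the changes. Leaving out an array ends the residual degrees of freedom of the blocked fit.

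The 4 named probe sets kept their direction in all alternatives. Only quantile normalization, median centring and cyclic loess could have turned it. The rule chose groups that did not overlap, and the other settings keep the order of the arrays. In the blocked ones Ag.2R.1440.0_CDS_at passed in 9 of 9, Ag.UNKN.267.0_CDS_at in 10 of 10, Ag.2R.65.0_CDS_a_at in 7 of 10 (limma adjusted p 0.0103 to 0.0721) and Ag.3L.178.0_CDS_s_at in 5 of 10 (0.0145 to 0.0925). The Plasmodium filters and comparison and the gene lists were not run. With no filter, r between the replicates' changes was 0.0534 and the replicates differed in 581 probe sets; the causes were not tested. Of all Ag. probe sets, 43.6% lay above background on all arrays, which limits what the dim ones can show.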

Other observations

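The tests of ID fields, brightness, controls and sibling probe sets in this part were chosen only after the results were seen. Some probe sets set single arrays or replicates far apart. On the CpG-ODN array of replicate 2, 4 tested probe sets lay at least 4-fold below each of the other 3 arrays, the farthest by 12.8-fold, while the other arrays had 0 such probe sets. Of the 4, 1 lay under the background level on that array. In 10 probe sets both replicate 1 arrays were at least 4-fold above both replicate 2 arrays, and in 0 the reverse; for 1 of the 10 both replicate 2 signals lay under background. The largest mean difference between the replicates, 19.4-fold, and the 12.8-fold gap were both measured above background.

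The IDs carry a field that reads 2L, 2R, 3L, 3R, X or UNKN. Of the 21 blocked calls, 8 had the field 2R, which 28.7% of tested probe sets carry, 5 had 3L, 4 had 3R, 2 had 2L, 2 had UNKN and 0 had X. No field passed Fisher's exact test (two-sided, 6 tests, Benjamini-Hochberg adjusted p from 0.510 to 1).

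The first pattern weighed is the difference between replicate numbers, with 281 probe sets called (1061 with treatment as a block). Brightness-dependent differences between arrays are argued against as the whole cause, since 240 of the 281 were still called after quantile normalization, which gives all arrays one distribution. A technical batch in hybridisation or labelling may contribute, as the hybridisation controls differed by 0.67 log2 between the buffer arrays. It cannot be told apart from separate cohorts of mosquitoes, because both would follow the replicate number.

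The second pattern is that changes with CpG-ODN tended to go together in the replicates (r = 0.206 over the tested probe sets, 0.0534 with no filter). A brightness trend of the arrays is argued against as the whole cause, because r was 0.195 after cyclic loess. Probe sets with the same ID stem (siblings) cannot weigh noise confined to single probe sets. The replicates lay on separate arrays, and independent noise would not make their changes go together. Over 816 pairs, the change of one in one replicate and of its sibling in the other correlated at 0.280. The same probe sets' own changes correlated slightly more closely between the replicates. Over 1000 random pairings the correlation between partners was at most 0.0951 in size. Siblings were also alike in brightness (r of their levels 0.715), which random pairings do not keep. The random pairings therefore cannot separate a change shared by siblings from one that follows brightness. A response to CpG-ODN may underlie what is left, as a hypothesis that these values do not decide, since handling that differed between treatments in both replicates was not tested. The hybridisation controls, which do not come from the mosquitoes, were higher with CpG-ODN by 0.12 and 0.13 log2 in replicates 1 and 2. The poly-A controls went in opposite directions (−0.10 and 0.32).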
